A study of Mus musculus with 12 samples.

How the data were processed

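RNA was measured in 12 subcutaneous mouse tumours grown from the lung cancer cell line 393P, in 4 groups of 3 libraries. The groups crossed the MAVS genotype of the injected cells (knockout or reconstituted) with treatment (control or the MPS1 inhibitor BAY-1217389). Per the labels' protocols, RNA was extracted with a spin column kit and a DNase step, and stranded libraries were made from polyadenylated RNA. The submitters' processing notes list Trimmomatic, HISAT2 and StringTie and the genome build GRCm38 (mm10), without versions and without the role of each tool. The deposited table holds whole-number counts per gene and library for 45777 genes under NCBI Gene IDs, not normalized by the authors as far as the values show. Whether the counting used strand, how it treated reads shared between genes, and whether a read pair counted as 1 or 2 are not given in the sources used here. On average 802 genes per library had a count of 2 and 658 a count of 1, as could arise where both mates of a pair are counted. Counts of 3 and 4 were found for 644.5 and 565 genes, without such an excess of the even value. Whether both mates were counted is thus not settled. The smallest step of the counts is uncertain, and sampling error derived from them may be a lower limit.

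Library totals ran from 52983715 to 69108411 counts, and 3 counts corresponded to 0.0434 to 0.0566 CPM. At least 1 count was found for 27547 genes. No pair of libraries within a group agreed within sampling noise, the smallest chi-square per gene being 33.9. Gene positions came from the RefSeq annotation of GRCm38.p6, in which 45679 of the gene IDs were found, 40671 of them under the same symbol.

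Groups were taken from the sample labels. The labels call the samples replicates without stating that each came from a separate animal, so the p-values measure the spread between these samples. All 12 libraries entered 1 model with a mean per group and no covariate. Low-count genes were removed with the filterByExpr function of edgeR 4.0.16, leaving 17885 genes, and TMM factors (0.920 to 1.03) were applied. Differences were tested with edgeR's quasi-likelihood F-test in R 4.3.3. Benjamini-Hochberg adjustment ran over all genes of a comparison, and a gene was called at an adjusted p below 0.05. Values are given as log2 differences with a standard error (SE) from the fit, or as CPM (counts scaled to a common library total with the TMM factors), as mean ± SD over the 3 libraries of a group.

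The 7 comparisons were the MPS1 inhibitor effect in each genotype, the MAVS effect under each treatment, the interaction of both, and each effect averaged over the other factor. Each of 32 gene lists with 701 genes in all (pathways of interferon signalling, antigen presentation, proliferation, stress and metabolism, and markers of the cell types a tumour piece can hold) was tested with camera of limma 3.58.1. The preset correlation between genes was 0.01, and adjustment ran over the 32 lists of a comparison. Camera compares the list with all other genes. For each list the number of called members is given over all genes tested and adjusted over the list alone. The lists, the tests and the rule for named genes were fixed before the data were examined.

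The rule for named genes had these parts. Mavs came first, in every library, and 18 fixed genes were given whatever their values, 1 of which is not reported here (the others were Mavs, Ttk, Ifnb1, Cxcl10, Ccl5, Isg15, Ifit1, Ifit3, Rsad2, Ddx58, Ifih1, H2-K1, Cd8a, Gzmb, Prf1, Cdkn1a and Mki67). Per comparison the rule took the 8 largest rises and the 8 largest falls among called genes with a mean log2 CPM of at least 1. Predicted genes (Gm with a number, Rik or LOC symbols) were left out there. The 3 libraries of one group had to lie above the 3 of the other, except for the interaction and the averaged effects. From each list that passed, or that had at least 2 called members, up to 4 members with the smallest p were eligible. Where no gene was called, the 3 with the smallest p were given as not passing.

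The fit was tested on simulated data before use. Counts were drawn from the real means, dispersions and library sizes with 200 of 17885 genes changed in the reconstituted MPS1 inhibitor group. For the MPS1 inhibitor effect in reconstituted tumours 66 of 100 genes changed by 1 log2 unit and 95 of 100 changed by 2 were called, with 6 false calls. For the MAVS effect under MPS1 inhibition these were 63 and 92, with 8 false calls, and for the interaction 35 and 91, with 4. A list of 50 genes shifted by 0.5 log2 units was found by camera, and 0 of 31 lists without a shift passed. Simulated genes varied independently, so this says nothing about lists whose genes vary together between libraries. All groups shared 1 dispersion per gene, and only genes with a mean above 1 CPM were changed. The real reconstituted inhibitor group held the replicate pair that differed most (SD of the log2 difference 0.948). The shares called may therefore be too high for comparisons with that group and for genes at lower counts.

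Alternatives planned beforehand were size factors of DESeq2 in the same fit, no filter on low counts, the Wald test of DESeq2 1.42.0, limma-voom, the replicate number as a block, only the 6 libraries of the groups compared, and each library left out in turn. For lists, camera with an estimated correlation and the fry test were run. Chosen after seeing the data were library quality weights in limma-voom, the mean of the skeletal muscle list as a covariate, and a fit without the 2 libraries at the ends of the first principal component. An exact permutation test of the list means per library for both averaged effects was added in the same way.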

Results

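Tumours grew from 393P, a mouse lung cancer cell line, injected under the skin of 8-week-old male 129S2/SvPasCrl mice. The cells lacked MAVS, the mitochondrial adaptor that relays signals from cytosolic RNA sensors, or carried MAVS again after reconstitution, by the genotype labels. Sample titles name the knockout group Luc, a name whose meaning is not given in the sources used here. Genotype goes with the injected cell population, so any other difference between the 2 populations would go with it too. The MAVS effects and the interaction below cannot be told apart from such a difference. Mice received control treatment or 5 mg/kg of BAY-1217389, an inhibitor of the spindle checkpoint kinase MPS1 (gene Ttk), 2 times daily for 2 days, and tumours were taken the next day. The stated aim was to find gene expression changes after pulsed MPS1 inhibition that depend on MAVS. Each of the 4 groups held 3 libraries, with total counts of 52983715 to 69108411 per library.

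Mavs (gene ID 228607, chromosome 2, 131234063 to 131248025 on GRCm38.p6) was read in all 12 libraries. The knockout control libraries held 40.5, 42.5 and 45.7 CPM and the knockout inhibitor libraries 43.5, 39.4 and 41.0 CPM. The reconstituted control libraries held 85.1, 68.9 and 59.1 CPM and the reconstituted inhibitor libraries 50.1, 53.8 and 62.8 CPM. Every reconstituted library lay above every knockout library, and the log2 difference averaged over treatments was 0.58 ± 0.09 (SE, edgeR adjusted p = 0.0105). Counts per gene do not separate the edited gene, the introduced copy and Mavs transcripts of host cells in the tumour pieces. They also do not show whether a transcript encodes a full protein. Ttk averaged 16.7 ± 1.60 CPM (SD, n = 3) in knockout controls and 17.6 ± 2.02 CPM (SD, n = 3) in reconstituted tumours under the inhibitor. Ifnb1, the gene of interferon beta, had 0 to 3 counts per library and was too low to test.

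**Figure D1:**
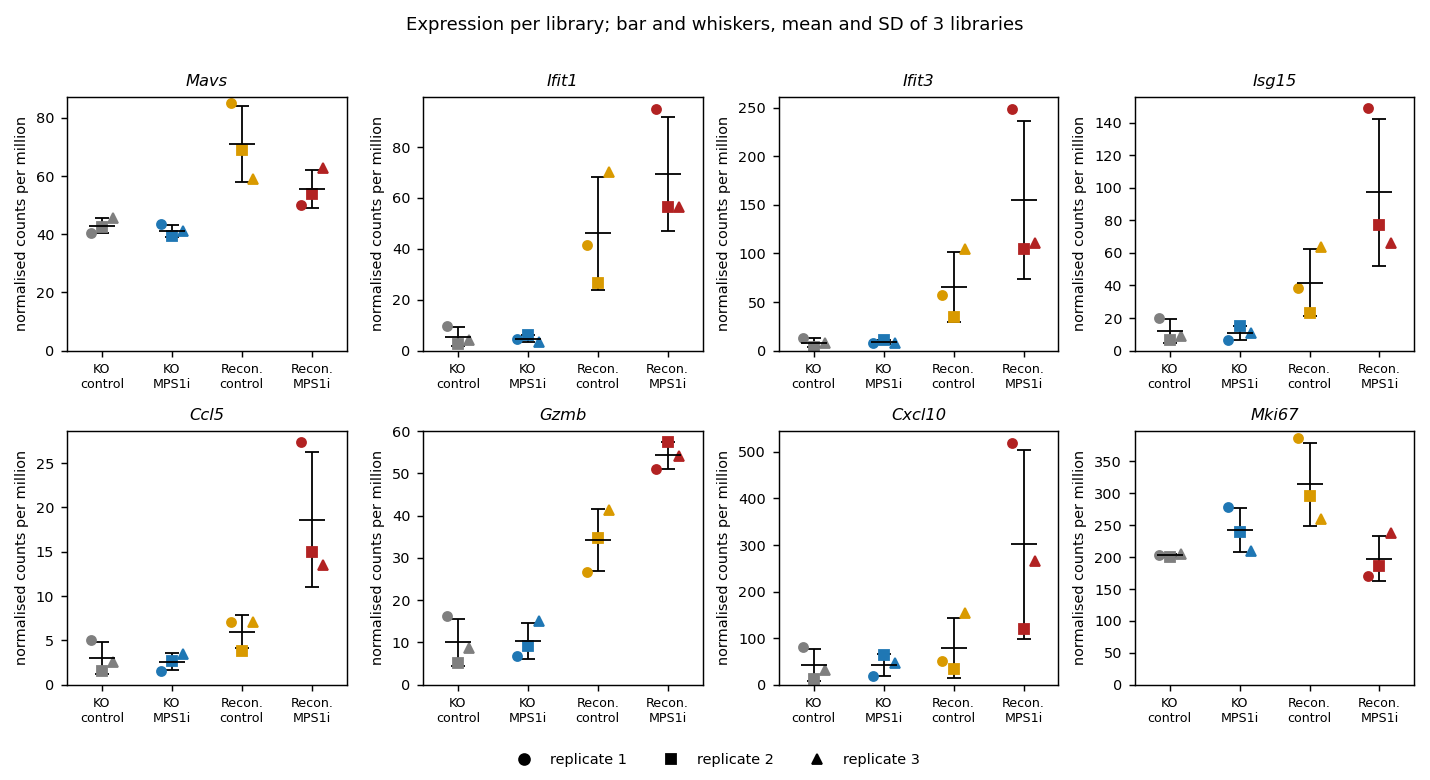
CPM (vertical axes, from 0) of 8 genes in each library of the 4 groups, KO standing for MAVS knockout and Recon. for MAVS reconstituted. Points are libraries, and bars and whiskers are the mean and SD of 3 libraries; Ifit1 averaged 4.62 CPM in knockout and 69.4 CPM in reconstituted tumours under the inhibitor.

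The MAVS effect under MPS1 inhibition was read from reconstituted against knockout tumours that both received the inhibitor. Interferon-stimulated genes were higher in reconstituted tumours. Ifit1, which binds viral RNA ends, averaged 69.4 ± 22.3 CPM (SD, n = 3) against 4.62 ± 1.36 CPM (SD, n = 3), a log2 difference of 3.91 ± 0.52 (SE). Differences of similar size were seen for Ifit3b (4.44), Ifit3 (4.12), the oligoadenylate synthetase gene Oas1g (3.98), Ifi27l2b (3.95), Sectm1b (3.93), Apol9b (3.69) and Apol9a (3.57). Members of the cytotoxic lymphocyte list were higher too, with granzyme B (Gzmb) at 2.39 ± 0.39, perforin (Prf1) at 2.72 ± 0.46 and Cst7 at 1.45 ± 0.21. Ccl5, which is in that list and in the chemokine list, had 2.85 ± 0.48. Counts of whole tumour pieces do not show which cells expressed these genes.

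Of 17885 genes, 93 were called higher and 23 lower in reconstituted tumours under MPS1 inhibition (edgeR, smallest adjusted p = 0.00754). The ubiquitin-like Isg15 reached 3.17 ± 0.53 and the RNA sensor Ddx58 (RIG-I) 1.13 ± 0.19, both at an adjusted p of 0.0316. The largest falls were the protocadherin gene Pcdhga3 (-3.00), the Wnt receptor gene Fzd4 (-1.40), the growth factor gene Hbegf (-1.37), the neurotrophin receptor gene Ntrk2 (-1.35), Dennd2a (-0.94), fibronectin (Fn1, -0.92), the granulocyte growth factor gene Csf3 (-0.91) and Rasgrp3 (-0.90). Log2 differences that did not pass were 2.84 for Cxcl10, 2.44 for Rsad2, 1.17 for H2-K1, 1.12 for Ifih1, 1.06 for Cd8a, 0.43 for Mavs, 0.42 for Cdkn1a, -0.08 for Ttk and -0.30 for Mki67. The Ifit, Oas1 and Apol9 genes have near-identical neighbours and the protocadherin gamma genes share exons, so their separate values are uncertain.

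All 50 type I interferon-stimulated genes had positive log2 differences under MPS1 inhibition, with a median of 2.02, and 31 were called (50 adjusted over the list alone). The camera adjusted p was 2.64e-87, against an adjusted p of 0.114 with an estimated correlation. In the RNA and DNA sensing pathway 27 of 30 genes were positive and 7 were called (19 adjusted over the list alone), among them Trim25 (0.80), Dhx58 (2.03) and Irf7 (2.71), with a camera adjusted p of 9.43e-18 and an adjusted p of 0.129 with an estimated correlation. The sensing list holds Mavs itself. It shares Dhx58, Irf7, Eif2ak2, Zbp1 and Oas1a with the interferon-stimulated list, so both lists are not independent results. Among cytotoxic lymphocyte and NK cell markers 20 of 21 were positive and 5 were called (16 adjusted over the list alone), with a camera adjusted p of 2.25e-15 and an adjusted p of 0.129 with an estimated correlation. The interferon-gamma response genes (median 1.91) and the MHC class I genes (median 1.20) were positive in 35 of 35 and 22 of 22 members with 0 called, and 33 and 22 were called adjusted over the list alone. Their camera adjusted p values were 8.04e-25 and 1.11e-17, and both had an adjusted p of 0.291 with an estimated correlation. Both hold Psmb8, Psmb9, Psmb10 and Nlrc5, so they are not independent results, here or in the other comparisons. The chemokine list shares Cxcl9, Cxcl10 and Cxcl11 with the interferon-gamma response list and Ccl5 with the cytotoxic list. Cd8a belongs to the cytotoxic and T cell lists.

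Lists that passed camera with smaller medians included T cell markers (0.81), T cell checkpoint genes (0.71), chemokines (0.54) and macrophage markers (0.33). Lists that passed in the other direction were fibroblast and pericyte markers (-0.70), mesenchymal transition genes (-0.33), endothelial markers (-0.28) and red blood cell markers (-1.20). In all, 13 lists passed higher and 4 lower, and 0 passed with an estimated correlation, these 8 having adjusted p values of 0.291 to 0.584. Without reconstituted inhibitor replicate 1 the medians of chemokines, fibroblast and pericyte markers and mesenchymal transition genes were 0.24, -0.34 and -0.11 (the last not passing), and macrophage markers had 0.20 without knockout inhibitor replicate 1. Mesenchymal transition genes (-0.50 without reconstituted inhibitor replicate 3), endothelial markers and red blood cell markers lost their calls without knockout inhibitor replicate 2, and the latter 2 also without reconstituted inhibitor replicate 3, red blood cell markers having -0.82 without knockout inhibitor replicate 3 (not passing). Skeletal muscle markers had a median of 1.44 in this comparison without passing (camera adjusted p = 0.586), which became -0.85 without reconstituted inhibitor replicate 1. The count of 116 fell to 0, 2 and 5 without the knockout inhibitor replicates 3, 1 and 2 and to 16, 52 and 58 without reconstituted inhibitor replicate 1, reconstituted control replicate 1 and knockout control replicate 3. It reached 223, 225 and 2816 without reconstituted control replicate 3 and reconstituted inhibitor replicates 2 and 3, 23 without the 2 libraries at the ends of the first component, and 1168 with DESeq2.

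The MAVS effect without MPS1 inhibition compared reconstituted with knockout control tumours. Interferon-stimulated genes were again higher, with Ifit3b at 3.54 ± 0.56, Ifi27l2b at 3.34 ± 0.43, Oas1g at 3.22 ± 0.37 and Ifit1 at 3.10 ± 0.50 (log2 ± SE). Samd9l rose from 39.8 ± 8.00 to 174 ± 32.1 CPM (SD, n = 3), a log2 difference of 2.13, and Oas1a (2.39) and Oas2 (2.12) passed as well. The clock gene Per1 rose by 1.33 ± 0.17. The stress gene Ier3 fell from 147 ± 33.9 to 44.7 ± 0.900 CPM (SD, n = 3), and the protease gene Prss22 (-1.22), Csf3 (-1.02) and the transcriptional repressor gene Tgif1 (-0.59) were also lower.

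In these controls 21 genes were called higher and 4 lower (edgeR, smallest adjusted p = 0.00778). Not passing were Ifit3 (3.02), Prf1 (2.53), Isg15 (1.81), Gzmb (1.78), Cd8a (1.42), Ifih1 (1.35), Rsad2 (1.35), Ddx58 (1.05), Ccl5 (0.97), Cxcl10 (0.91), Mavs (0.73), Mki67 (0.63), Ttk (0.25), H2-K1 (0.10) and Cdkn1a (-0.32), at adjusted p values of 0.0644 or above. All 50 type I interferon-stimulated genes were positive, 7 were called (38 adjusted over the list alone), and the median was 1.22 (camera adjusted p = 3.11e-51, adjusted p = 0.211 with an estimated correlation). The RNA and DNA sensing pathway had a median of 0.50 with 1 gene called, Oas1a (camera adjusted p = 9.26e-14, adjusted p = 0.211 with an estimated correlation). Oas1a is also a member of the interferon-stimulated list. The cytotoxic lymphocyte list had a median of 0.70 with 0 called (camera adjusted p = 1.90e-06, adjusted p = 0.344 with an estimated correlation), which was 0.27 without reconstituted control replicate 3 and 1.40 without knockout control replicate 1.

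In controls 6 lists passed camera as higher and 11 as lower in reconstituted tumours, and 0 passed with an estimated correlation. All 22 hypoxia and glycolysis genes had negative log2 differences (median -0.55, 0 called, 17 adjusted over the list alone), among them Egln3 (-2.48) and the glucose transporter gene Slc2a1 (-0.82), with a camera adjusted p of 9.26e-14 and an adjusted p of 0.310 with an estimated correlation. Senescence-associated secretory genes were negative in 24 of 25 members (median -0.65, 0 called, 9 adjusted over the list alone), with a camera adjusted p of 6.80e-10 and an adjusted p of 0.211 with an estimated correlation. Ribosomal protein genes (median -0.38, camera adjusted p = 1.63e-15) and oxidative phosphorylation genes (median -0.26, camera adjusted p = 1.02e-07) were lower, while mitosis genes (0.26, camera adjusted p = 4.65e-06) and S phase genes (0.22, camera adjusted p = 1.32e-05) were higher. These 4 lists had adjusted p values of 0.366, 0.459, 0.459 and 0.527 with an estimated correlation, and mitosis genes had 0.12 without reconstituted control replicate 1. Chemokines (-0.66, and -0.20 without knockout control replicate 2), NF-kB genes (-0.19, and -0.32 to -0.13 with single libraries left out) and macrophage markers (-0.24, passing in 7 of 12 fits with a library left out) were lower by camera, against 0.54 for chemokines and 0.33 for macrophage markers under the inhibitor. Lower were also red blood cell (-1.76), neutrophil (-0.44) and epithelial tumour cell markers (-0.20) and immediate early genes (-0.15), and these 7 lists had adjusted p values of 0.310 to 0.565 with an estimated correlation. The neutrophil median changed sign with a single library left out. Interferon-gamma response genes had a median of 0.73 (camera adjusted p = 0.00163, adjusted p = 0.709 with an estimated correlation), which became -0.0378 without reconstituted control replicate 3, 0.40 without knockout control replicate 2 (neither passing) and 1.14 without knockout control replicate 1.

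Without MPS1 inhibition the count of 25 was 0 without knockout control replicate 2, 9 without reconstituted control replicate 1 or 3, 10, 11 and 13 without the knockout inhibitor replicates 1, 2 and 3, 12 without reconstituted control replicate 2, and 13 and 15 without knockout control replicates 3 and 1. It was 54 and 80 without reconstituted inhibitor replicates 1 and 3, 15 with limma-voom, 10 with only the 6 libraries compared and 721 with DESeq2. The called genes of both MAVS comparisons overlapped in 15 higher genes against 0.109 for independent lists (Fisher's exact test, p = 8.88e-31) and in 1 lower gene, Csf3, against 0.00514. These comparisons share no library, but both use the spread per gene pooled over all 12 libraries in 1 fit. Fisher's exact test treats genes as independent, while genes of a pathway can vary together between libraries. Its p-value therefore does not measure the spread between samples. Skeletal muscle markers had a median of 0.63 in the controls without passing (camera adjusted p = 0.963). Across all genes the log2 differences correlated at r = 0.16 (Pearson) and -0.09 (Spearman), with the same sign in 41.2% of genes, which are not independent replicates.

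Averaged over treatments, interferon-stimulated, RNA sensing and cytotoxic genes were higher with MAVS. Oas1g (3.60 ± 0.27), Ifi27l2b (3.64 ± 0.30), Ifit3b (3.99 ± 0.40), Ifit3 (3.57 ± 0.39), Ifit1 (3.50 ± 0.36), Ifi44 (3.23 ± 0.39), Apol9b (3.12 ± 0.44) and Ifit1bl1 (3.06 ± 0.35) were the leading rises on the log2 scale. The RNA sensors Ifih1 (MDA5, 1.23 ± 0.17) and Ddx58 (1.09 ± 0.14) and the RNA-editing enzyme gene Adar (0.85 ± 0.11) rose as well. Prf1 (2.62 ± 0.32), granzyme A (Gzma, 2.28 ± 0.38), Gzmb (2.09 ± 0.27) and Ccl5 (1.91 ± 0.33) were higher. The hypoxia-induced prolyl hydroxylase gene Egln3 fell by 1.59, and the growth factor genes Hbegf, Pgf and Areg fell by 1.27, 1.05 and 0.94.

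Over all tumours 195 genes were called higher and 84 lower with MAVS (edgeR, smallest adjusted p = 2.57e-04). Isg15 (2.49) and Rsad2 (1.89) passed. Further falls were Pcdhga2 (-2.74), Pcdhga1 (-2.37), Pcdhga3 (-1.36), the receptor kinase gene Ret (-1.09) and the signalling inhibitor gene Spry4 (-1.03). Values that did not pass were Cxcl10 (1.88), Cd8a (1.24), H2-K1 (0.63), Mki67 (0.17), Ttk (0.09) and Cdkn1a (0.05). Of 50 type I interferon-stimulated genes 39 were called higher (49 adjusted over the list alone), of 30 sensing genes 12 (20 adjusted over the list alone), and of 21 cytotoxic markers 5 (17 adjusted over the list alone). These 3 lists had camera adjusted p values of 4.39e-149, 9.58e-33 and 1.29e-21 and passed with an estimated correlation too, at adjusted p values of 0.0228, 0.0298 and 0.0446. The sensing list shares members with the interferon-stimulated list and holds Mavs, itself called, so it is not an independent result.

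An exact permutation test of the mean per library within treatments gave differences of 1.79 and 0.69 for the interferon-stimulated and sensing lists at p = 0.005 each, two-sided, the smallest the 400 arrangements can give. The cytotoxic list differed by 1.23 at p = 0.01 in the same exact permutation test, and after adjustment over 32 lists these were 0.08, 0.08 and 0.107. Senescence-associated secretory genes were lower (median -0.53), with Areg, Plau and Igfbp3 called (9 adjusted over the list alone), a camera adjusted p of 2.15e-08 and an adjusted p of 0.172 with an estimated correlation. Interferon-gamma response genes (median 1.30, and 0.85 without reconstituted control replicate 3) and MHC class I genes (0.72) passed camera, with adjusted p values of 0.222 and 0.260 with an estimated correlation, and in all 8 lists passed camera as higher and 7 as lower. In the same comparison other cell type lists had exact permutation differences of 0.49 for T cell markers (p = 0.045), 0.46 for T cell checkpoint genes (p = 0.02), -0.52 for fibroblast and pericyte markers (p = 0.045), -0.43 for neutrophil markers (p = 0.05) and -1.08 for red blood cell markers (p = 0.05), at adjusted p values of 0.128 to 0.16. Senescence-associated secretory genes had -0.45 in the exact permutation test (p = 0.015, adjusted p = 0.12). Among epithelial tumour cell markers Cldn4 fell by 0.57 and Epcam by 0.35, the list itself not passing (camera adjusted p = 0.052). The count of 279 was 147 without knockout control replicate 2, 115, 146 and 148 without knockout inhibitor replicates 1, 2 and 3, 168 without reconstituted control replicate 3, 170 without the 2 libraries at the ends of the first component and 953 with DESeq2.

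**Figure D2:**
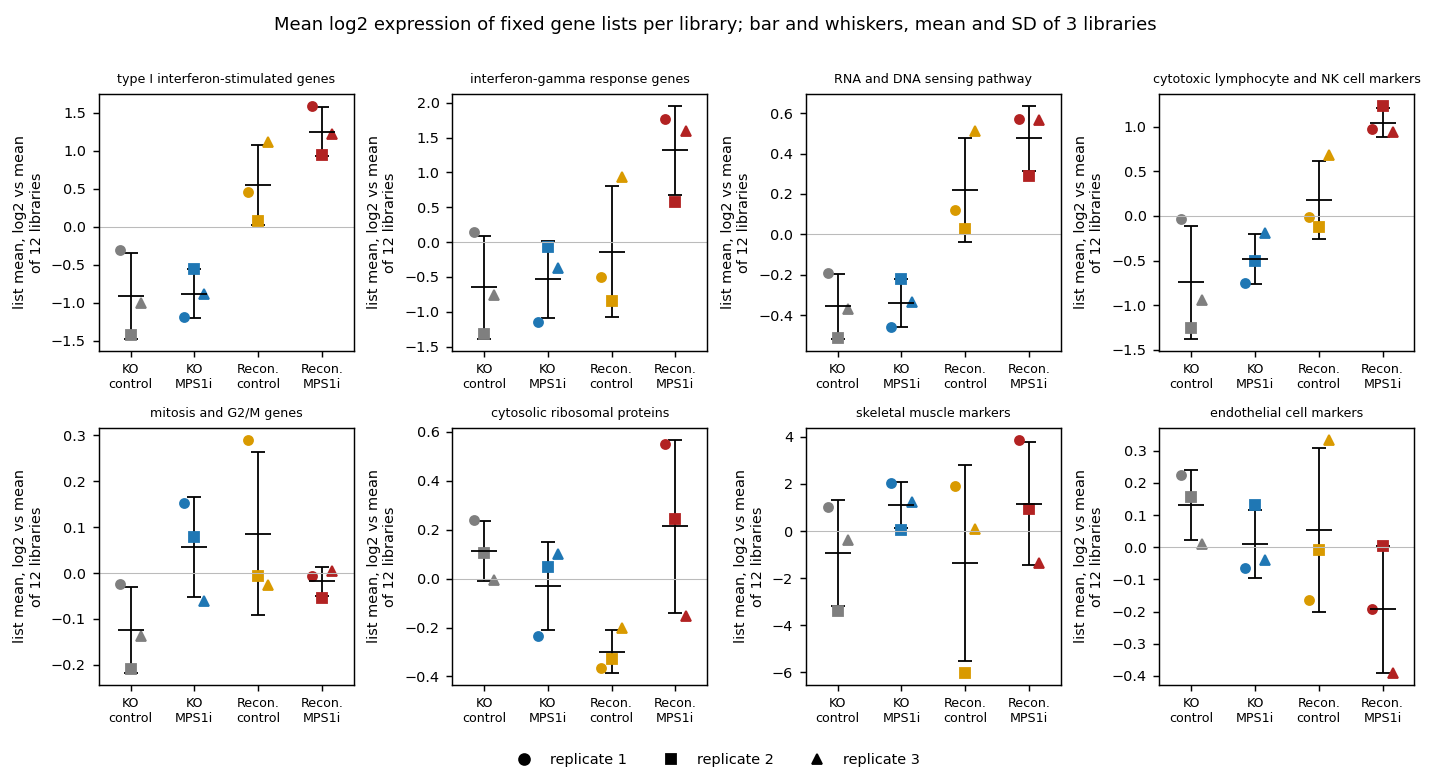
Mean log2 expression of 8 fixed gene lists in each library (vertical axes, relative to the mean of all 12 libraries), KO standing for MAVS knockout and Recon. for MAVS reconstituted, with bars and whiskers for the mean and SD of 3 libraries. Every reconstituted library lies above every knockout library for type I interferon-stimulated genes, and skeletal muscle markers range from -6.04 to 3.88 across libraries.

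The MPS1 inhibitor effect in reconstituted tumours was read against reconstituted controls, and edgeR called 0 genes (5827 at an unadjusted p below 0.05), against 3495 with DESeq2, 0 with limma-voom and 5812 with limma-voom and quality weights. Among the fixed genes, the chemokine gene Cxcl10 had 79.2 ± 64.6 CPM in controls and 301 ± 203 CPM under the inhibitor (SD, n = 3 each), a log2 difference of 1.93 ± 0.78 (SE, adjusted p = 0.119). Others were Ccl5 (1.64 ± 0.45, adjusted p = 0.0729), Cd8a (1.73 ± 0.71), Ifit3 (1.25 ± 0.50), Isg15 (1.22 ± 0.49) and H2-K1 (1.01 ± 0.34), while Prf1 (0.10), Ddx58 (0.08) and Ifih1 (0.01) were near 0. The proliferation marker Mki67 had -0.67 ± 0.16 and the cell cycle inhibitor gene Cdkn1a 0.57 ± 0.16, both at an adjusted p of 0.0729.

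By list, interferon-gamma response genes had positive values in 34 of 35 members (median 1.45), with Socs1 at 2.14 and Nos2 at 1.78. MHC class I genes were positive in 22 of 22 (median 1.01), with H2-T23 at 1.30 and B2m at 1.08. With 0 members called, 13 and 18 members passed adjusted over the list alone, camera adjusted p values were 1.60e-11 and 4.66e-10, and both had an adjusted p of 0.469 with an estimated correlation. Type I interferon-stimulated genes (median 0.62), chemokines (0.69), cytotoxic markers (0.85), T cell markers (0.62) and macrophage markers (0.33) also passed camera as higher, with adjusted p values of 0.469 to 0.497 with an estimated correlation. Ribosomal protein genes were positive in 38 of 38 members (median 0.51, 36 adjusted over the list alone), with a camera adjusted p of 3.64e-16 and an adjusted p of 0.469 with an estimated correlation. Oxidative phosphorylation (0.50), hypoxia and glycolysis (0.46), NF-kB (0.23), integrated stress response (0.18) and MHC class II genes (0.45) were higher by camera, with adjusted p values of 0.469 to 0.537 with an estimated correlation.

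Endothelial markers (median -0.26), among them Cdh5 (-0.68), Tek (-0.96) and Kdr (-0.58), and fibroblast and pericyte markers (-0.45) were lower by camera under the inhibitor, with adjusted p values of 0.511 and 0.469 with an estimated correlation. In total 14 lists passed higher and 2 lower, and 0 passed with an estimated correlation (smallest adjusted p = 0.469). Skeletal muscle markers were among the higher lists (median 1.96, camera adjusted p = 0.00784, adjusted p = 0.573 with an estimated correlation). Their median became -0.28 without reconstituted inhibitor replicate 1, 1.37 without reconstituted control replicate 2 (neither passing) and 3.38 without reconstituted control replicate 1.

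Without reconstituted inhibitor replicate 1 and reconstituted control replicate 2 together, the MPS1 inhibitor effect in reconstituted tumours had medians of 0.26 for type I interferon-stimulated genes, 0.82 for interferon-gamma response genes, 0.67 for MHC class I genes, 0.34 for ribosomal protein genes, 0.21 for hypoxia and glycolysis genes, -0.23 for fibroblast and pericyte markers and 0.03 for NF-kB genes, the last not passing. Without reconstituted control replicate 3 they were 0.99 for type I interferon-stimulated genes, 2.23 for interferon-gamma response genes, 1.05 for T cell markers, 1.32 for cytotoxic markers and -0.09 for endothelial markers, the last not passing. Type I interferon-stimulated genes had 0.40 without reconstituted control replicate 2. Without reconstituted inhibitor replicate 1 ribosomal protein genes had 0.33, hypoxia and glycolysis genes 0.27 and fibroblast and pericyte markers -0.24, the latter having -0.72 without replicate 2 of that group. Without its replicate 3 macrophage markers had 0.53, the integrated stress response list had 0.27, as without reconstituted control replicate 1, and endothelial and MHC class II genes did not pass, the latter also not without reconstituted control replicate 1.

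The smallest adjusted p with edgeR was 0.0729, shared by 1288 genes. Unadjusted, 5827 genes had p below 0.05, against 894 expected on average where no gene differs. The number was 2025 without the 2 libraries at the ends of the first component and 3257 to 7788 with single libraries left out. Genes can vary together between libraries, so such a number can lie far from 894 by chance. Here and in the comparisons below it is not a test of an effect. The 3 genes with the smallest p, not passing, were Gm45927 (-1.60), Cdh5 (-0.68) and Pcdh17 (-1.58). The other fixed genes, not passing, were Gzmb (0.66), Ifit1 (0.59), Rsad2 (0.57), Ttk (-0.18) and Mavs (-0.35). Other tools called 0 genes (limma-voom), 5812 (limma-voom with library quality weights) and 3495 (DESeq2). Leaving out reconstituted inhibitor replicate 3 gave 5683 calls, against 3 without replicate 2 of that group, 2 without reconstituted control replicate 3, 1 without knockout control replicate 3 and 0 without each of the others.

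**Figure D3:**
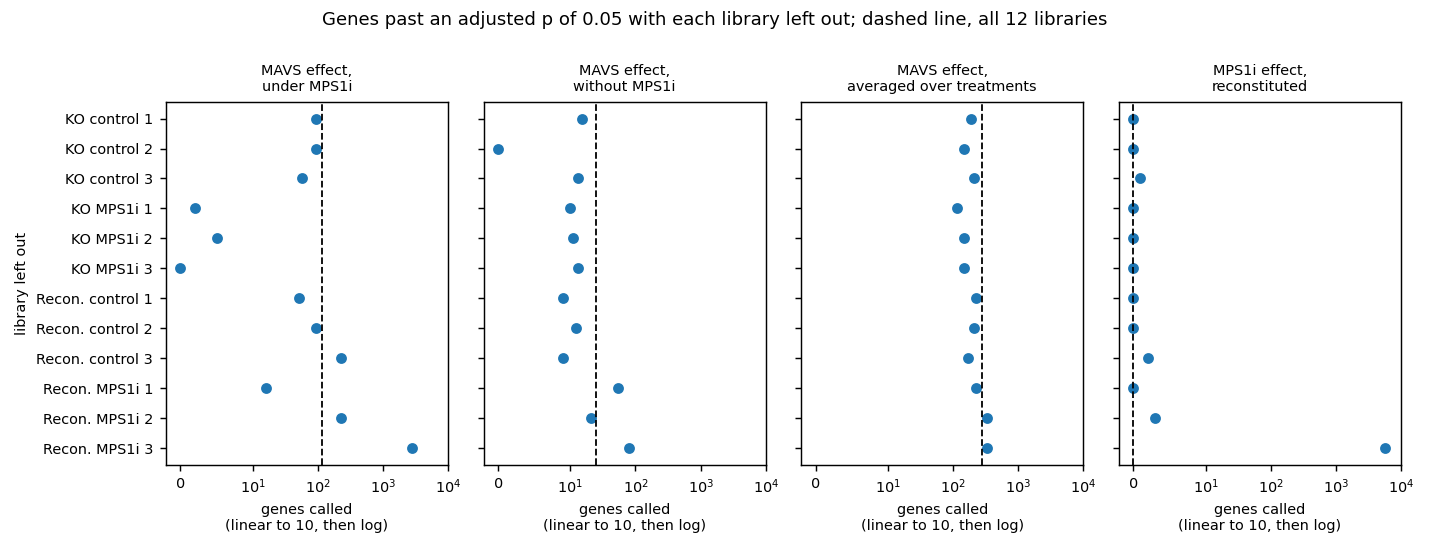
Genes with an adjusted p below 0.05 (horizontal axes, linear to 10 and logarithmic above) with each of the 12 libraries left out in turn (rows, KO standing for MAVS knockout and Recon. for MAVS reconstituted), for 4 comparisons. Dashed lines mark the counts with all libraries, and in the panel of the MPS1 inhibitor effect in reconstituted tumours the count goes from 0 to 5683 without reconstituted inhibitor replicate 3.

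The MPS1 inhibitor effect in knockout tumours did not pass for any of the interferon genes fixed beforehand, with standard errors too wide to exclude moderate changes. Log2 differences were 0.15 ± 0.51 (SE) for Ifit3, -0.14 ± 0.50 for Isg15, -0.22 ± 0.48 for Ifit1, -0.52 ± 0.57 for Rsad2, 0.00 ± 0.76 for Cxcl10 and -0.24 ± 0.46 for Ccl5, with adjusted p values of 1. Type I interferon-stimulated genes had a median of -0.02, which went from -0.24 to 0.34 with single libraries left out, the highest without knockout control replicate 1, where the list passed camera. Mitosis genes were positive in 34 of 34 members, with a median of 0.20 and examples in the kinesin genes Kif20a (0.33), Kif2c (0.27) and Kif11 (0.26). S phase genes were positive in 28 of 32 members (median 0.12). Hypoxia and glycolysis genes were negative in 22 of 22 members (median -0.20) and ribosomal protein genes in 36 of 38 (median -0.12).

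With 0 members called in each, also adjusted over the list alone, these 4 lists had camera adjusted p values of 1.49e-13, 3.12e-06, 5.68e-06 and 1.14e-05. With an estimated correlation their adjusted p values were 0.820, 0.820, 0.820 and 0.890. Hypoxia and glycolysis genes had -0.03 without knockout control replicate 2 (not passing) and -0.31 without replicate 3 of that group, and S phase genes had 0.06 and 0.22 without its replicates 2 and 1. Ribosomal protein genes had -0.04 and -0.18 without knockout inhibitor replicates 1 (not passing) and 3 and -0.06 without knockout control replicate 1. Lower by camera in knockout tumours were also macrophage markers (-0.18, and -0.25 to -0.07 with single libraries left out), senescence-associated secretory genes (-0.20, -0.35 to -0.08), chemokines (-0.26, -0.60 to -0.06), NF-kB genes (-0.10, -0.15 to -0.06) and endothelial markers (-0.13, -0.18 to -0.08), and T cell markers were higher (0.13, -0.0227 to 0.28). Each of these 6 lists lost its call without at least 1 of the knockout libraries. Skeletal muscle markers were higher by camera in this comparison too (median 1.16, camera adjusted p = 8.25e-07, adjusted p = 0.820 with an estimated correlation), with 2.45 and 0.64 without knockout control replicates 1 and 2 (the latter not passing) and 0.64 without knockout inhibitor replicate 1. No list passed with an estimated correlation (smallest adjusted p = 0.820), 11 having passed camera.

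No gene was called in knockout tumours with edgeR, and 305 genes had an unadjusted p below 0.05 against 894 by chance. DESeq2 called 3 genes and limma-voom 1, with and without quality weights. Not passing at the smallest p were Gm7030 (0 counts in every library but those of the knockout controls, at 1.34 ± 0.471 CPM, SD, n = 3), Pcdhga3 (1.88) and Ccdc150 (9, 6 and 16 counts in knockout controls and 0 under the inhibitor). The other fixed genes had log2 differences of 2.10 (Cd8a), 0.26 (Mki67), 0.24 (Ifih1), 0.16 (Ttk), 0.05 (Gzmb), -0.01 (Ddx58), -0.06 (H2-K1), -0.06 (Mavs), -0.09 (Prf1) and -0.17 (Cdkn1a).

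The interaction asked whether the MPS1 inhibitor effect differed between the genotypes. Interferon-gamma response genes had a median interaction of 1.29 log2 units, positive in 34 of 35 members, with Socs1 at 2.23, Ido1 at 3.02 and Pdcd1lg2 at 2.84. MHC class I genes (1.03), chemokines (1.15, with Ccl24 at 3.95 and Ccl4 at 1.98) and type I interferon-stimulated genes (0.70) were positive in 22 of 22, 26 of 28 and 47 of 50 members. Ribosomal protein genes were positive in 38 of 38 members (0.65) and hypoxia and glycolysis genes in 22 of 22 (0.60). Mitosis genes were negative in 26 of 34 members (-0.32), with Mki67 at -0.93 and Hmmr at -0.89.

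These 7 lists passed camera at adjusted p values of 3.01e-07, 2.00e-06, 1.02e-05, 2.09e-05, 1.24e-16, 2.35e-07 and 4.85e-05, and none of the 32 passed with an estimated correlation (smallest adjusted p = 0.580). No member was called over all genes, and adjusted over the list alone 8 chemokines, 32 ribosomal protein genes, 11 hypoxia and glycolysis genes and 8 mitosis genes passed. Without knockout control replicate 1 the median interaction was 0.29 for type I interferon-stimulated genes, 0.65 for interferon-gamma response genes and 0.63 for MHC class I genes, and without the 2 libraries at the ends of the first component it was 0.26, 0.66 and 0.65. Chemokines had 0.71 without knockout control replicate 2, mitosis genes -0.21 without reconstituted control replicate 1, and interferon-gamma response genes 2.18 without replicate 3 of that group. Skeletal muscle markers had a median interaction of 0.66 without passing (camera adjusted p = 0.645), which went from -1.47 to 2.13 with single libraries left out.

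For single genes edgeR called 0 interactions (smallest adjusted p = 0.144), limma-voom 0, limma-voom with quality weights 3405 and DESeq2 1239. Unadjusted p was below 0.05 for 4421 genes, against 894 by chance. The smallest p values, not passing, belonged to Gm45927 (-2.33), Ntrk2 (-2.22) and Pcdhga3 (-3.29). Fixed genes, not passing, were Cxcl10 (1.92), Ccl5 (1.88), Isg15 (1.36), Ifit3 (1.09), Rsad2 (1.09), H2-K1 (1.07), Ifit1 (0.81), Cdkn1a (0.74), Gzmb (0.61), Prf1 (0.19), Ddx58 (0.08), Ifih1 (-0.23), Mavs (-0.30), Ttk (-0.34) and Cd8a (-0.36). The count went to 4005 without reconstituted inhibitor replicate 3 and to 1 without reconstituted control replicate 3. Across genes the inhibitor's log2 differences in the 2 genotypes correlated at r = -0.05 (Pearson) and -0.26 (Spearman), with the same sign in 36.3% of genes, which are not independent replicates. The Spearman value was -0.02 and -0.05 without replicate 1 of the knockout inhibitor and knockout control groups and -0.36 without knockout inhibitor replicate 3, and the Pearson value went from -0.09 to 0.10 with single libraries left out.

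Averaged over genotypes, the MPS1 inhibitor effect passed camera for some lists, none of which passed with an estimated correlation (smallest adjusted p = 0.5) or, after adjustment, in the exact permutation test of the list means. Interferon-gamma response genes had positive values in 34 of 35 members (median 0.72) and MHC class I genes in 22 of 22 (0.48), with 0 called. T cell markers (0.34), with Cd3d at 0.81 and Trbc2 at 0.61, and cytotoxic markers (0.42) had positive medians. Endothelial markers had negative values in 17 of 18 members (-0.19), with Cdh5 at -0.39. Camera adjusted p values of these 5 lists were 5.73e-15, 5.23e-12, 5.85e-07, 1.05e-06 and 1.71e-05, with an adjusted p of 0.5 for each with an estimated correlation. The exact permutation test gave p = 0.13, 0.12, 0.065, 0.055 and 0.075 (adjusted p = 0.497 each). In knockout tumours alone the medians of interferon-gamma response and MHC class I genes were 0.07 and -0.01, against 1.45 and 1.01 in reconstituted tumours, and went from -0.20 to 0.47 and from -0.21 to 0.33 with single libraries left out. Without reconstituted control replicate 3 these lists had averaged medians of 1.10 and 0.72, T cell markers had 0.20 without knockout inhibitor replicate 3 and cytotoxic markers 0.79 without knockout control replicate 1. Skeletal muscle markers were higher by camera (median 1.58, camera adjusted p = 4.92e-08, adjusted p = 0.5 with an estimated correlation, exact permutation p = 0.175), with a median of 0.43 without reconstituted inhibitor replicate 1 and 0.14 without the 2 libraries at the ends of the first component (not passing). Adjusted over the list alone, 3 T cell markers and 1 endothelial marker passed, and 0 genes of the other 3 lists. Of the interferon genes themselves 2 could be tested, with a median of 0.97 (camera adjusted p = 0.0243, adjusted p = 0.5 with an estimated correlation), not passing without knockout inhibitor replicate 2 or reconstituted inhibitor replicate 3.

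No gene was called for the averaged MPS1 inhibitor effect with edgeR (smallest adjusted p = 0.522), and 1399 had an unadjusted p below 0.05 against 894 by chance. That number fell below 894 with the muscle covariate (468) and without the 2 libraries at the ends of the first component (584). With single libraries left out it went from 650 to 4857. DESeq2 called 1 gene and limma-voom 0, with and without quality weights. The genes with the smallest p, not passing, were Cdh5, Trdv4 (-3.37) and 1700001J03Rik (-3.32). Fixed genes, not passing, were Cd8a (1.92), Cxcl10 (0.97), Ccl5 (0.70), Ifit3 (0.70), Isg15 (0.54), H2-K1 (0.48), Gzmb (0.36), Cdkn1a (0.20), Ifit1 (0.19), Ifih1 (0.13), Ddx58 (0.04), Rsad2 (0.03), Prf1 (0.00), Ttk (-0.01), Mavs (-0.20) and Mki67 (-0.20). The count was 3 without reconstituted inhibitor replicate 3 and 1 without knockout control replicate 3 or reconstituted control replicate 3.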

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

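Of the tests given here, those with the muscle list as a covariate were chosen after the data were seen, and leaving out single libraries was planned but chosen as a test of the interferon-gamma response genes only after the result was seen. The 16 gene lists below passed the camera test of the interaction, so the MPS1 inhibitor effect differed between the genotypes by that test, and none did so with an estimated correlation (smallest adjusted p = 0.580). Median interaction values above 0 were 1.29 for interferon-gamma response genes, 1.15 for chemokines, 1.03 for MHC class I genes, 0.70 for type I interferon-stimulated genes, 0.65 for ribosomal protein genes, 0.65 for oxidative phosphorylation genes and 0.60 for hypoxia and glycolysis genes. Smaller ones were 0.59 for cytotoxic lymphocyte markers, 0.44 for macrophage markers, 0.43 for senescence-associated secretory genes, 0.41 for NF-kB genes, 0.22 for unfolded protein and integrated stress response genes and 0.15 for immediate early genes. Values below 0 were -0.43 for fibroblast and pericyte markers, -0.32 for mitosis genes and -0.20 for S phase genes. With a library left out in turn, the cytotoxic, fibroblast and S phase lists passed camera in 8 of 12 fits and immediate early genes in 7, the medians going from -0.73 to -0.18 for the fibroblast list, from -0.27 to -0.10 for the S phase list and from 0.08 to 0.37 for immediate early genes. Without knockout control replicate 1 the medians were 0.08 for cytotoxic markers (not passing) and 0.29 for type I interferon-stimulated genes.

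Ribosomal protein genes had negative values under the inhibitor in knockout tumours and positive ones in reconstituted tumours, with a median interaction of 0.65. With the muscle list as a covariate the median was 0.62 (SE between libraries 0.241), above 0.5 of the value without it by more than 1 SE, which argues against muscle in the tumour pieces as the whole cause. A trend on transcript length and GC content, fitted per library on genes outside all lists with all 38 members covered, took the median from 0.63 (SE 0.245) to 0.32 (SE 0.133). It stayed above 0 by more than 2 SE, but lay too close to 0.5 of the first value to decide how much a length and GC trend could account for. A biological effect of MAVS and the inhibitor on these genes stays open as a hypothesis.

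Reconstituted inhibitor replicates 1 and 3 differed more than other replicate pairs, with an SD of their log2 difference across 16583 genes of 0.948, against 0.555 to 0.777 for the other 11 pairs within groups. Leaving out replicate 3 gave 5683 calls for the inhibitor in reconstituted tumours. A trend on transcript length and GC took 10.5% of the variance of that difference, below the share set for it beforehand, which argues against it as the whole cause, although both pairs holding replicate 3 had higher shares (10.5% and 10.6%) than the other 10 pairs (0.437% to 5.95%). With the muscle covariate edgeR called 0 genes (4045 at an unadjusted p below 0.05), but it called 0 without it too (5827), so this count decides nothing about muscle. Muscle in the tumour pieces, a difference between tumours or a library batch may remain, and no label separates them.

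Interferon-gamma response genes had a median interaction of 1.29, with an SE of the list mean between libraries of 0.848. Without single libraries it went from 0.65 (without knockout control replicate 1) to 2.18, so no library alone brought it to 0, and with the muscle covariate it was 1.14 (SE 0.832). Since the value lies within 2 SE of 0 in both fits, a single library and muscle in the tumour pieces cannot be told apart from a difference between genotypes here. A MAVS-dependent response is a candidate explanation that the spread between libraries leaves open.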

How the results depend on the processing

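Library quality weights, the muscle covariate and the fit without reconstituted inhibitor replicate 1 and reconstituted control replicate 2 were chosen after seeing the data. A gene is counted as turned where it passed before or after, and a list where it passed with all libraries. Size factors of DESeq2, no filter and the muscle covariate kept every count of called genes within 1.5 times. Where the main count was 0, staying at 0 shows nothing about robustness. With the muscle covariate, genes at an unadjusted p below 0.05 went from 5827 to 4045 for the inhibitor in reconstituted tumours. They went from 1399 to 468 for the averaged inhibitor effect, from 4421 to 4229 for the interaction and from 305 to 311 in knockout tumours. Counts for the MPS1 inhibitor effect in reconstituted tumours (0) became 5812 with quality weights, 3495 with DESeq2 and 1 with the 6 libraries compared, and 0 to 5683 with single libraries left out. In knockout tumours (0) they became 1 with limma-voom, 1 with quality weights and 3 with DESeq2, and stayed 0 with each library left out. For the interaction (0) they were 3405 with quality weights, 1239 with DESeq2 and 0 to 4005 with single libraries left out. Under MPS1 inhibition the MAVS count of 116 (80.2% higher) became 43 with the replicate block, 934 with quality weights (48.0% higher), 1168 with DESeq2 (60.2% higher), 23 without the pair of libraries (91.3% higher), 64 with the 6 libraries compared (95.3% higher) and 0 to 2816 with single libraries left out. Without the inhibitor the count of 25 (84.0% higher) became 15 with the replicate block, 15 with limma-voom (73.3% higher), 2097 with quality weights (46.6% higher), 721 with DESeq2 (42.7% higher), 10 with the 6 libraries compared (50.0% higher) and 0 to 80 with single libraries left out. The averaged inhibitor effect (0) gave 1 with DESeq2 and 0 to 3 with single libraries left out. The averaged MAVS count of 279 (69.9% higher) became 736 with quality weights (54.8% higher), 953 with DESeq2 (59.8% higher), 170 without the pair and 115 to 331 with single libraries left out. The replicate numbers were tested as a pairing: 9 of 18 same-number pairs of libraries correlated above 0.1 (range -0.113 to 0.308) and 6 of 12 libraries correlated best with their own number. The highest value, 0.341, belonged to libraries with different numbers, but a smaller share of such pairs lay above 0.1. Pairing by number is therefore not excluded, and the main fit did not use it. With the replicate block the averaged MAVS count was 207 and counts of 0 stayed 0. With an estimated correlation 0 lists passed in 6 comparisons and 3 in the averaged MAVS effect. With fry 0 lists passed for the 4 comparisons of the inhibitor, 4 for MAVS under the inhibitor, 5 without it and 6 averaged. In knockout tumours 6 to 14 lists passed with single libraries left out, against 11. Among lists that passed with all libraries, the medians that turned were skeletal muscle markers in reconstituted tumours under the inhibitor (1.96, -0.86 without the pair, -0.28 to 3.38 with single libraries left out) and in knockout tumours (1.16, -0.12 with the muscle covariate, which holds these genes), T cell markers in knockout tumours (0.13, -0.0227 without knockout inhibitor replicate 3, -0.0227 to 0.283), interferon-gamma response genes for MAVS without the inhibitor (0.73, -0.0378 without reconstituted control replicate 3, -0.0378 to 1.14), neutrophil markers there (-0.44, 0.0235 without the pair, -0.556 to 0.0201), hypoxia genes for the averaged inhibitor effect (0.11, -0.0074 without the pair) and ribosomal protein genes for the averaged MAVS effect (-0.07, -0.17 to 0.0069). Lists that had not passed could turn and pass: without the pair, skeletal muscle markers had -0.85 for MAVS under the inhibitor (1.44 before) and -2.06 in the interaction (0.66 before), and without reconstituted control replicate 1 they had -0.84 for MAVS without the inhibitor (0.63 before). In knockout tumours under the inhibitor, type I interferon-stimulated genes (-0.02) and MHC class I genes (-0.01) passed at 0.34 and 0.33 without knockout control replicate 1. Averaged MAVS medians of the macrophage, NF-kB and immediate early lists, all within 0.05 of 0, also changed sign and passed without single libraries. The correlation between both inhibitor responses (-0.05) went from -0.0904 to 0.104 with single libraries left out. Of the values of named genes under all alternatives 3481 kept direction and side of the threshold, 500 lost the call, 85 gained one and 0 turned, and of list values 1629 kept, 324 lost and 9 turned. With a library left out its group has 2 libraries and the spread is pooled over all groups. The cause of these changes was not tested. Genes near 3 counts, such as Ifnb1, were limited by depth.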

Other observations

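Among the tests here, the one on glucocorticoid-induced genes was chosen only after Per1 and Tsc22d3 were seen, and the clock gene lists were also set up after the data were seen. Averaged over treatments, single members of lists that did not pass were called in both directions with MAVS. Of the p53 target genes the kinase gene Plk2 fell by 0.73, the stress gene Gadd45a by 0.60 and the cell death gene Pmaip1 by 0.39, while the list had a median of -0.03 (camera adjusted p = 0.052). Of the immediate early genes Ier3 fell by 0.92 and Jun by 0.39 and Zfp36 rose by 0.51 (list camera adjusted p = 0.411). Among macrophage markers the interferon-induced Siglec1 rose by 0.90 and Ms4a6c by 0.51, and the list median was near 0 (camera adjusted p = 0.145). Red blood cell markers had a median of -1.48 with all 6 members negative (camera adjusted p = 3.74e-05, adjusted p = 0.222 with an estimated correlation). B and plasma cell, dendritic cell, skin epithelium and adipocyte markers and p53 target genes passed in 0 of the 7 comparisons.

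Per1 and Tsc22d3, both induced by glucocorticoids, rose by 1.33 and 0.99 in reconstituted over knockout controls. If exposure to glucocorticoids differed, other induced genes should be higher as well. The 16 other members tested had a median of 0.0264 (SE of the list mean between libraries 0.189), with 8 above 0 and 0 called (camera p = 0.874, p = 0.929 with an estimated correlation). Fkbp5 had 0.40, Sgk1 0.46 and Mt2 -1.63, none passing, so a glucocorticoid difference may or may not be present. Time of day of collection is another candidate explanation: clock genes of the Dbp phase had a median of -0.10 and those of the Arntl phase 0.16, a difference of -0.26 with an SE of 0.193, which does not settle it.

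Other splits of the same libraries were fitted to see how often they called as many genes. The MAVS effect under MPS1 inhibition called 116 genes, and the highest of the other 9 splits of the 6 libraries called 0, the real one being 1 of 10. Without the inhibitor 25 genes were called against 1 in the highest other split, again 1 of 10. Both inhibitor effects within a genotype called 0 genes, as did each of the 10 splits. With 10 splits no share under 0.05 can be reached.

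For the MAVS effect averaged over treatments, 2 of 100 drawn splits of the genotype labels within treatments called at least 279 genes, the real one included. Drawn splits can carry the interaction, as the other of these 2 did, so their number does not exclude chance. The other split called 3112 genes. It set knockout controls, knockout inhibitor replicate 3 and reconstituted inhibitor replicates 1 and 2 against the rest. That swaps the genotype labels of the controls, which turns the averaged MAVS effect into the interaction, and exchanges replicate 3 between the inhibitor groups. The interaction itself called 4005 genes without reconstituted inhibitor replicate 3. Why this split called so many genes was not tested. The interaction and the averaged inhibitor effect called 0 genes, so each of 100 splits gave as many by construction and their number decides nothing, the highest others calling 279 and 22. The split with 279 swaps the genotype labels of the controls alone, which turns the interaction into the averaged MAVS effect.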
